A study of Homo sapiens with 4 samples.

How the data were processed

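Gene-level RNA-seq counts of 4 libraries were analysed, 2 from T98G cells carrying a vector and 2 from T98G cells overexpressing LGP2. T98G is an established human glioblastoma line. The labels list its cell type as astroblastoma. Their growth text speaks of 293T cells, while every title and the cell line field name T98G. RNA was isolated with TRIzol and libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. The labels give the replicate numbers 2 and 3 in both groups, and libraries of any other number were not analysed here. They do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

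The authors deposited raw read counts per gene, with 1 column per library, human gene symbols and no coordinates. The submitters' processing notes name the genome build mm10, a mouse build, although the symbols are human. The aligner, the counter, the annotation and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart with certainty, and genes that share exons with another gene are treated as uncertain. Each of the 20913 genes in the table had a read in at least 2 of the 4 libraries. Library totals ran from 56033379 to 63932198 counts.

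Symbols were matched to GENCODE release 29 on GRCh38, 19831 of them exactly and 464 through older symbols, while 618 had no match. All coordinates, GC contents, transcript lengths and shared exons come from that reference, which may not be the annotation used for counting. A gene was taken to share an exon where an exon overlapped one of another gene on the same strand, which held for 3584 genes.

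Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, filterByExpr by group and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. The filter left 17863 genes and removed 3050, and the tested genes held 99.98% of all counts. CPM values use the TMM-scaled library totals. Standard errors (SE) of log2 fold changes were taken from the test's F statistic, and 95% intervals use its total degrees of freedom. A fold against a group in which every library had 0 counts was set against a floor of 3 counts per library and is a lower bound. Intervals and floors cover no error beyond that model or counting.

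Before the data were examined, 36 gene lists were written from general knowledge of RNA sensing, glioma and common cell states. None was chosen on these samples. DHX58 was left out of every list, and each list had at least 5 tested genes. Lists were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation and fry were alternatives. With so few libraries, the test with an estimated correlation has few residual degrees of freedom and little power. Members were also adjusted over the list alone. A list's score in a library is the mean over its genes of the log2 CPM minus the gene's mean over the 4 libraries, with a prior count of 2.

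Genes were named by a rule fixed at the same time. It takes DHX58 first. It adds up to 10 called protein-coding genes with the largest rise and up to 10 with the largest fall, at a mean of at least 5 CPM and with groups that do not overlap. From each list it takes up to 2 called members per direction, and up to 4 called members in the direction of a list that passed, but no list had a called member. For the interferon, RNA sensing, NF-kB and chemokine lists without a called member, it takes the 2 members with the highest mean. The members named for the lists that passed, up to 4 per list with the smallest p in the direction of the list, were chosen after their values were seen, as were all other genes named in the text.

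Alternatives fixed before the data were examined were the replicate number as a block, leaving out each library in turn, DESeq2 size factors or upper-quartile scaling in edgeR, no filter, a filter of at least 5 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a log2 fold change of at least 1 and an adjusted p under 0.01. GC and length offsets (natural splines with 5 degrees of freedom per library) and leaving out genes that share exons were added later. GC content and length were known for 97.9% of the tested genes. A fit that leaves out a library holds a single library in one group and takes its spread only from the other group. Adjusted p-values and calls from such fits therefore do not measure the spread in the group left with a single library.

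The fit was tested on simulated data, in 5 simulations with counts drawn from the real means and totals and 200 genes with a mean of at least 1 CPM changed in each, on 17176 to 17267 tested genes. It recovered 16.0% of genes changed 1.5-fold, 59.6% at 2-fold, 92.0% at 4-fold and 96.4% at 8-fold, with a median of 10 false calls per simulation. DESeq2 recovered 22.4%, 70.4%, 94.0% and 96.4%, with a median of 26 false calls. With 200 genes changed, the Benjamini-Hochberg cut was less strict than in the real data, where edgeR called 3 genes. These rates may therefore overstate the recovery in the real comparison. With no list moved, camera called 2 lists in all 5 simulations together, and it found the interferon-stimulated genes in 5 of 5 simulations when these were moved 1.25-fold. Simulated genes varied independently of each other. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.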

Results

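Transcript levels were measured by RNA-seq in T98G cells, a human glioblastoma line, carrying either a vector or an LGP2 expression construct. LGP2, the product of DHX58, is an RNA helicase of the RIG-I-like receptor family, which binds double-stranded RNA and lacks the signalling domains of RIG-I and MDA5. There were 2 libraries per group. Library totals were 63932198 and 59663219 counts for vector replicates 2 and 3, and 56033379 and 63300173 counts for LGP2 overexpression replicates 2 and 3. Mitochondrially encoded genes took 3.72% and 3.85% of counts in the vector libraries and 4.50% and 3.95% in the LGP2 overexpression libraries. Correlations of log2 CPM between libraries, taken across genes, were 0.969 within the vector group, 0.969 within the overexpression group and 0.969 on average between groups. The series asks how LGP2 acts in glioma development, and the only comparison its design holds is LGP2 overexpression against vector.

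DHX58 itself was 68.3-fold higher in the overexpressing cells. The gene lies at chromosome 17, 42101404 to 42112733, on the minus strand (GENCODE 29, GRCh38), is protein coding and shares no exon with another gene there. Its counts were 377 and 571 in the vector libraries and 30509 and 34045 in the LGP2 overexpression libraries. Its level went from 7.80 ± 2.26 CPM (SD, n = 2) to 533 ± 13.7 CPM (SD, n = 2). The log2 fold change was 6.09 (SE 0.24, 95% interval 5.57 to 6.62, adjusted p = 1.9e-06 by edgeR's quasi-likelihood test). Reads from the construct and from the cell's own gene cannot be separated in these counts.

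**Figure D1:**
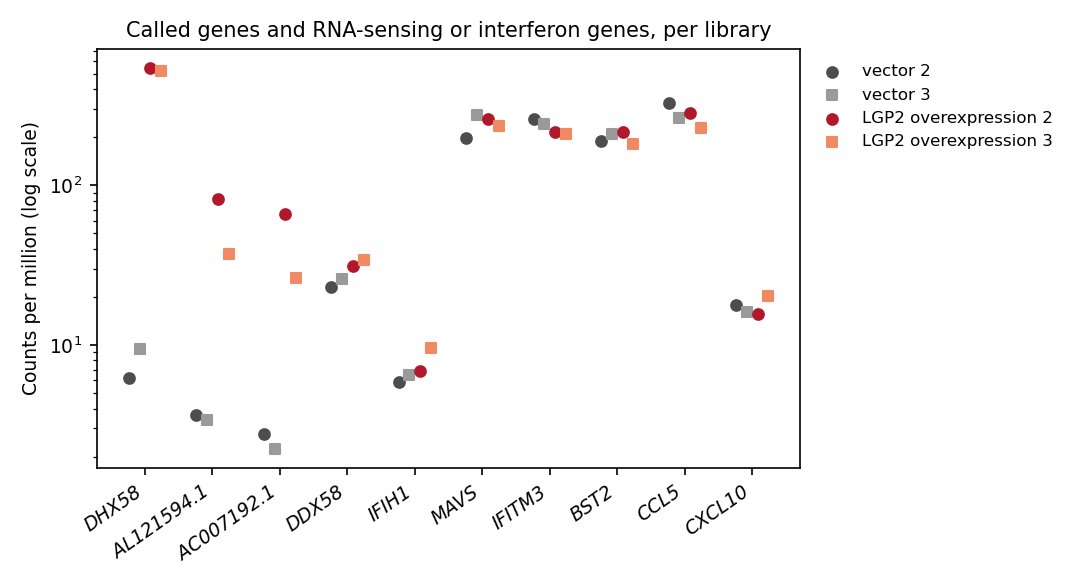
CPM on a log axis for the 3 called genes and for RNA-sensing, interferon-stimulated and chemokine genes, with 1 point per library. DHX58 was at 6.20 and 9.40 CPM in the vector libraries and at 542 and 523 CPM in the LGP2 overexpression libraries, while the sensing, interferon and chemokine genes shown did not pass the test.

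Apart from DHX58, 2 genes rose and 0 fell among the 17863 genes tested with edgeR. AL121594.1 rose from 3.51 ± 0.161 CPM to 59.9 ± 32.3 CPM (SD, n = 2 per group), a log2 fold change of 4.09 (SE 0.35, adjusted p = 0.00247). AC007192.1 rose from 2.50 ± 0.371 to 46.1 ± 27.8 CPM (SD, n = 2 per group), a log2 fold change of 4.20 (SE 0.40, adjusted p = 0.00416). In GENCODE 29 both are protein-coding genes on the plus strand that share exons with other genes, so their counts are uncertain. AL121594.1 spans chromosome 14, 35122549 to 35317474, and shares exons with PRORP, which encodes a mitochondrial tRNA-processing nuclease, and PSMA6, which encodes a proteasome subunit. AC007192.1 spans chromosome 19, 18153158 to 18178117, and shares exons with PIK3R2, which encodes a regulatory subunit of PI3 kinase, and IFI30, which encodes an interferon-inducible lysosomal thiol reductase. The log2 fold changes of these partners were -0.55 for PRORP, -0.29 for PSMA6, -0.75 for PIK3R2 and -0.22 for IFI30, and none of them passed. Without LGP2 overexpression replicate 2 neither gene passed, with log2 fold changes of 3.40 for each. That fit has a single LGP2 library and takes its spread from the vector pair. The lost calls therefore do not show that the rise rests on the library left out. Both calls also ended with no filter, with log2 fold changes of 4.10 and 4.21 (adjusted p = 0.945 and 0.9996).

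The next adjusted p after the called genes was 0.119. At an unadjusted p under 0.05, 536 genes were higher and 260 lower, 796 in all, where 893 would be expected by chance. DESeq2 called 14 genes higher and 9 lower, and limma-voom 4 and 2. The biological coefficient of variation common to all genes was 25.9%. The median SE of a log2 fold change was 0.23, and for 10911 genes (61.1%) the 95% interval excluded a 2-fold change in either direction. Counts of called genes moved with single libraries: edgeR called 42 higher and 36 lower without vector replicate 2, 291 and 141 without vector replicate 3, 1 and 1 without LGP2 overexpression replicate 2, and 5 and 2 without LGP2 overexpression replicate 3.

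**Figure D2:**
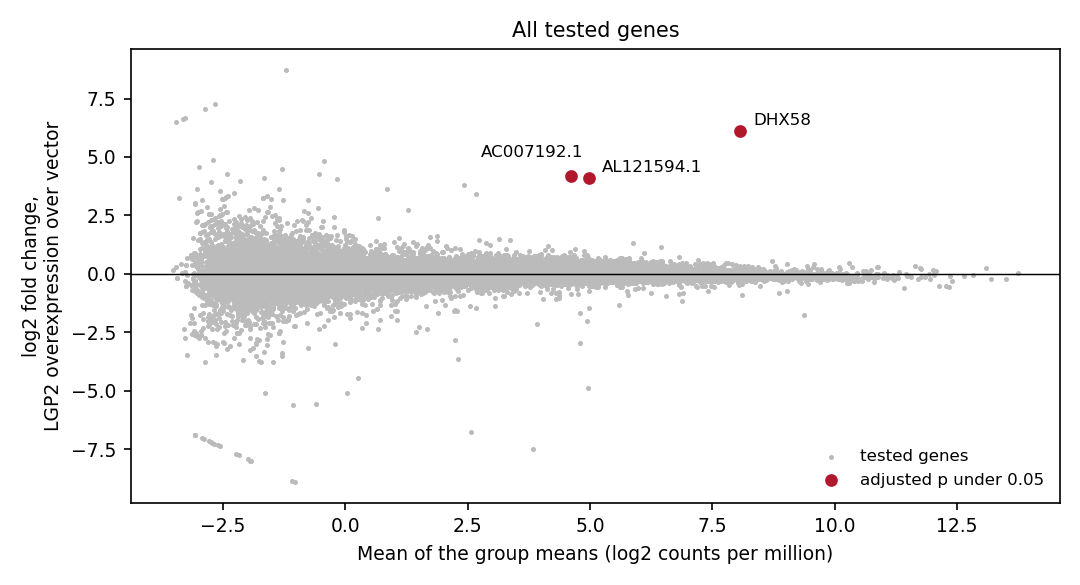
Log2 fold change of LGP2 overexpression over vector against the mean level in log2 CPM, with 1 point per tested gene. The 3 red points are the called genes, with DHX58 at a log2 fold change of 6.09.

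None of the gene lists for the pathways LGP2 belongs to passed the set test with all libraries in the fit. Of the 54 interferon-stimulated genes, the antiviral genes induced by interferon signalling, 33 lay above 0 and 21 below, with a median log2 fold change of 0.04 (camera, adjusted p = 0.233). IFITM3, which blocks virus entry, was at 252 ± 13.7 CPM in vector and 214 ± 3.84 CPM in overexpressing cells, and BST2, which tethers budding virus, at 200 ± 13.6 and 198 ± 24.0 CPM (SD, n = 2 per group). For 44 of the 54 genes the 95% interval excluded a 2-fold rise, and for 42 it excluded a 2-fold change in either direction. The list's score was -0.17 in vector replicate 2 and between 0.04 and 0.07 in the other libraries. Without vector replicate 3 this list passed with a median of 0.12 (adjusted p = 0.0263), and without vector replicate 2 its test direction turned downward at a median of 0.02 (adjusted p = 0.839). The 26 tested RNA sensing and MAVS signalling genes split 13 above and 13 below 0, with a median of -0.0039 against a mean of 0.05 and an upward test direction (adjusted p = 0.859), and for 24 of them the interval excluded a 2-fold change. MAVS, the adaptor of RIG-I and MDA5, had a log2 fold change of 0.08 (SE 0.18), which was -0.14 without vector replicate 2, and PRKRA, an activator of the kinase PKR, -0.06 (SE 0.13). The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) were at 24.5 ± 1.94 and 6.21 ± 0.446 CPM in vector and 32.8 ± 2.12 and 8.22 ± 1.85 CPM with LGP2 (SD, n = 2 per group), with log2 fold changes of 0.42 (SE 0.18) and 0.41 (SE 0.26) that did not pass. These last 2 genes were chosen after their values were seen.

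Cytokine and inflammatory genes gave no set call either. The 12 interferon and interferon receptor genes had a median log2 fold change of -0.10 against a mean of -0.40 (camera, adjusted p = 0.412). Their lowest member was at -3.10, but 0 members had an unadjusted p under 0.05. The list's scores were 0.18 and 0.14 in vector and -0.16 and -0.15 with LGP2. The median ran from -0.18 without LGP2 overexpression replicate 2 to 0.0026 without vector replicate 2. IFNGR2, a chain of the interferon-gamma receptor, was at -0.11 (SE 0.14) and the kinase JAK1 at 0.09 (SE 0.16). The 28 NF-kB and inflammatory response genes had a median of -0.12, with 19 below 0 (adjusted p = 0.109). The chemokine CXCL8 was at 700 ± 452 CPM in vector and 647 ± 359 CPM with LGP2 (SD, n = 2 per group), and SOD2, a mitochondrial superoxide dismutase, had a log2 fold change of -0.09 (SE 0.17). The direction of CXCL8 depended on single libraries, with a log2 fold change of 0.77 without vector replicate 2 and 0.36 without LGP2 overexpression replicate 2. Against that, CXCL8 was at -0.66 without vector replicate 3 and -0.83 without LGP2 overexpression replicate 3. Without vector replicate 2, IFNGR2 was at -0.01, JAK1 at -0.08 and SOD2 at 0.07. The NF-kB list passed as lower without vector replicate 3 (median -0.23, adjusted p = 2.4e-06) and without LGP2 overexpression replicate 3 (median -0.17, adjusted p = 0.00769), but its direction turned upward without vector replicate 2 (median 0.07, adjusted p = 0.260) and without LGP2 overexpression replicate 2 (median 0.03, adjusted p = 0.999999). The 5 interferon-induced chemokines had a median of -0.20 (adjusted p = 0.233), which ran from -0.37 without LGP2 overexpression replicate 2 to -0.07 without vector replicate 2, with CCL5 at -0.20 (SE 0.17) and CXCL10 at 0.08 (SE 0.20). Without 1 library CCL5 ran from -0.37 without LGP2 overexpression replicate 2 to -0.04 without vector replicate 2, and CXCL10 was at -0.11 without LGP2 overexpression replicate 3. The 24 antigen presentation genes had a median of -0.06 (adjusted p = 0.442), which ran from -0.12 without LGP2 overexpression replicate 2 to -0.0032 without vector replicate 2. No member of these or the RNA sensing and interferon-stimulated lists passed over all genes tested or adjusted over the list alone by edgeR, and none was called by DESeq2 or limma-voom. At an unadjusted p under 0.05, 4 interferon-stimulated, 2 RNA sensing and 2 antigen presentation genes were higher and 1 NF-kB gene was lower.

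Immediate early genes, transcription factors and feedback regulators induced within minutes of growth factor or serum stimulation, were lower as a set with LGP2. Of 20 tested members 18 lay below 0, with a median log2 fold change of -0.42 (camera, adjusted p = 2.3e-10). With an estimated correlation the adjusted p was 0.735. EGR1, a zinc-finger factor driven by ERK signalling, was at 6.99 ± 1.26 CPM in vector and 2.36 ± 0.790 CPM with LGP2 (SD, n = 2 per group), with a log2 fold change of -1.57 (SE 0.33). The log2 fold change was -0.75 (SE 0.25) for DUSP1, a phosphatase of MAP kinases, -0.63 (SE 0.20) for KLF10, a repressor induced by TGF-beta, and -0.54 (SE 0.17) for IER2. No member passed over all genes tested, 1 passed adjusted over the list alone (EGR1, adjusted p = 0.0128), and 11 had an unadjusted p under 0.05, all of them lower. DESeq2 also called EGR1 (adjusted p = 0.0205), and limma-voom called no member. Without vector replicate 3 EGR1, DUSP1, KLF10 and IER2 were at log2 fold changes of -1.75, -1.10, -0.88 and -0.73. Without vector replicate 2 they were at -1.37, -0.29, -0.34 and -0.33. These members, like those named for the other lists that passed, were chosen for their small p after their values were seen. Leaving out any 1 library kept the call, with medians of -0.22 without vector replicate 2, -0.55 without vector replicate 3, -0.66 without LGP2 overexpression replicate 2 and -0.34 without LGP2 overexpression replicate 3.

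Growth factor signalling and matrix genes were also lower as sets. Of 28 growth factor receptor and RAS-ERK genes 22 lay below 0, with a median log2 fold change of -0.19 (camera, adjusted p = 0.00657, and adjusted p = 0.735 with an estimated correlation). The 34 extracellular matrix and mesenchymal genes had 26 below 0 and a median of -0.18 (adjusted p = 0.00751, and adjusted p = 0.735 with an estimated correlation). The transcription factor MYC was at 90.5 ± 21.6 CPM in vector and 66.2 ± 8.46 CPM with LGP2, and fibronectin (FN1) at 223 ± 46.1 and 149 ± 11.7 CPM (SD, n = 2 per group). The proteoglycan biglycan (BGN) had a log2 fold change of -0.56 (SE 0.19), SNAI1, a repressor of epithelial genes, -0.46 (SE 0.21) and COL6A3 -0.38 (SE 0.18). The receptors ERBB3, IGF1R and EPHA2 had log2 fold changes of -1.67 (SE 0.74), -0.32 (SE 0.20) and -0.40 (SE 0.24), and without vector replicate 2 ERBB3 was at -0.79 and EPHA2 at 0.14. Without vector replicate 3 MYC, EPHA2, FN1 and BGN were at log2 fold changes of -0.68, -0.79, -0.78 and -0.69. Without vector replicate 2 MYC was at -0.19, FN1 at -0.35 and BGN at -0.41. SNAI1 was at -0.28 without LGP2 overexpression replicate 3 and IGF1R at -0.19 without vector replicate 3. No member of either list passed over all genes tested or adjusted over the list alone by edgeR, and none was called by DESeq2 or limma-voom, while 2 members of each list were lower and 1 matrix gene was higher at an unadjusted p under 0.05. Both calls ended without vector replicate 2, where the medians shrank to -0.11 for the RAS-ERK list and -0.06 for the matrix list (adjusted p = 0.121 for each). They also ended without LGP2 overexpression replicate 2, at medians of -0.19 and -0.21 (adjusted p = 0.0752 and 0.0697), and without LGP2 overexpression replicate 3, at -0.20 and -0.15 (0.0502 and 0.0878).

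Replication-dependent histone genes and ribosomal protein genes were lower as sets, and so were the few microglia and macrophage markers. Of 17 histone genes 14 lay below 0, with a median of -0.51 (camera, adjusted p = 2.4e-04, and adjusted p = 0.735 with an estimated correlation). Their levels were low, with a median over genes of 1.67 CPM in vector and 1.57 CPM with LGP2. The filter of at least 5 CPM in 2 libraries left too few of them to test. H2BC21 and H2BC8 had log2 fold changes of -1.44 (SE 0.39) and -1.58 (SE 0.46), and both passed adjusted over the list alone, which no other histone gene did. Without vector replicate 2 they were at -0.69 and -0.91, and without vector replicate 3 at -1.93 and -2.04. Without LGP2 overexpression replicate 2 H2BC8 was at -2.32. All 32 ribosomal protein genes lay below 0, between -0.26 and -0.08, with a median of -0.15 (adjusted p = 5.8e-04, and adjusted p = 0.735 with an estimated correlation) and no member at an unadjusted p under 0.05. Their score was 0.26 in vector replicate 2 and -0.13 in vector replicate 3, on either side of -0.07 and -0.06 in the LGP2 overexpression libraries. Of 16 microglia and macrophage markers 5 were analysed here, with a median of -0.29 (adjusted p = 0.0320, and adjusted p = 0.735 with an estimated correlation). CD14 was the lowest member, also when set at its bound, so the bound could not move the median. The set test was not rerun with CD14 at its bound or left out, so the call may rest on it. CD14 had 25 and 16 counts in vector and 0 and 0 with LGP2, at least 6.79-fold lower, and it was the 1 member that passed adjusted over the list alone, while CD68 was at 104 ± 15.2 and 84.9 ± 6.84 CPM (SD, n = 2 per group). No member passed over all genes tested by edgeR or was called by DESeq2 or limma-voom, and at an unadjusted p under 0.05 there were 2 lower histone genes and 1 lower marker. The histone call ended without vector replicate 2 (median -0.28, adjusted p = 0.119) and without LGP2 overexpression replicate 3 (median -0.35, adjusted p = 0.0504). The ribosomal call turned upward and ended without vector replicate 2 (median 0.07, adjusted p = 0.204), and its median was -0.33 without vector replicate 3. It also ended without LGP2 overexpression replicate 2, where the median stayed at -0.15 (adjusted p = 0.0587), and with GC and length offsets (median -0.066, adjusted p = 0.128). The marker call ended without any 1 of the libraries (medians from -0.55 to -0.13, adjusted p from 0.0636 to 0.283), with no filter (median -0.28, adjusted p = 0.0552), and with GC and length offsets (median -0.20, adjusted p = 0.0811).

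DNA damage repair, heat shock and mitochondrially encoded genes were higher as sets. Of 35 DNA damage repair genes 30 lay above 0, with a median log2 fold change of 0.17 (camera, adjusted p = 6.0e-05, and adjusted p = 0.735 with an estimated correlation). The damage checkpoint kinase ATR was at 15.0 ± 2.28 CPM in vector and 24.9 ± 1.06 CPM with LGP2, and ATM at 21.9 ± 4.54 and 32.4 ± 0.216 CPM (SD, n = 2 per group). BRIP1, a helicase that binds BRCA1, and FANCI, a Fanconi anaemia protein, had log2 fold changes of 0.72 (SE 0.26) and 0.35 (SE 0.14). Without 1 library the log2 fold change ran from 0.48 to 0.93 for BRIP1 and from 0.37 to 0.79 for ATM. The 12 heat shock genes had 9 above 0 and a median of 0.20 (adjusted p = 0.0254, and adjusted p = 0.735 with an estimated correlation). The chaperones HSPH1, HSP90AA1 and HSPD1 had log2 fold changes of 0.47 (SE 0.18), 0.46 (SE 0.21) and 0.33 (SE 0.18), which were 0.25, 0.17 and 0.15 without LGP2 overexpression replicate 3 and 0.65, 0.70 and 0.49 without LGP2 overexpression replicate 2. All 13 mitochondrially encoded genes lay above 0, with a median of 0.26 (adjusted p = 6.0e-05, and adjusted p = 0.735 with an estimated correlation). MT-ATP8, MT-ND4L, MT-ATP6 and MT-ND2 had log2 fold changes of 0.32, 0.31, 0.31 and 0.29, which were 0.11, 0.19, 0.15 and 0.12 without LGP2 overexpression replicate 2. No member passed over all genes tested or adjusted over the list alone by edgeR, and none was called by DESeq2 or limma-voom, although 4 repair genes and 1 heat shock gene were higher at an unadjusted p under 0.05. Without vector replicate 3 ATR and HSPH1 were at log2 fold changes of 0.89 and 0.64, and without vector replicate 2 at 0.58 and 0.31. Without vector replicate 2 the repair call ended (median 0.09, adjusted p = 0.121), and its median was 0.42 without vector replicate 3 and 0.27 without LGP2 overexpression replicate 2. The heat shock call ended without vector replicate 3 (median 0.05, adjusted p = 0.257) and without LGP2 overexpression replicate 3 (median 0.14, adjusted p = 0.343). The mitochondrial call ended without LGP2 overexpression replicate 2 (median 0.12, adjusted p = 0.506), the library whose score of 0.27 stood apart from -0.14, -0.10 and -0.03 in the others.

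**Figure D3:**
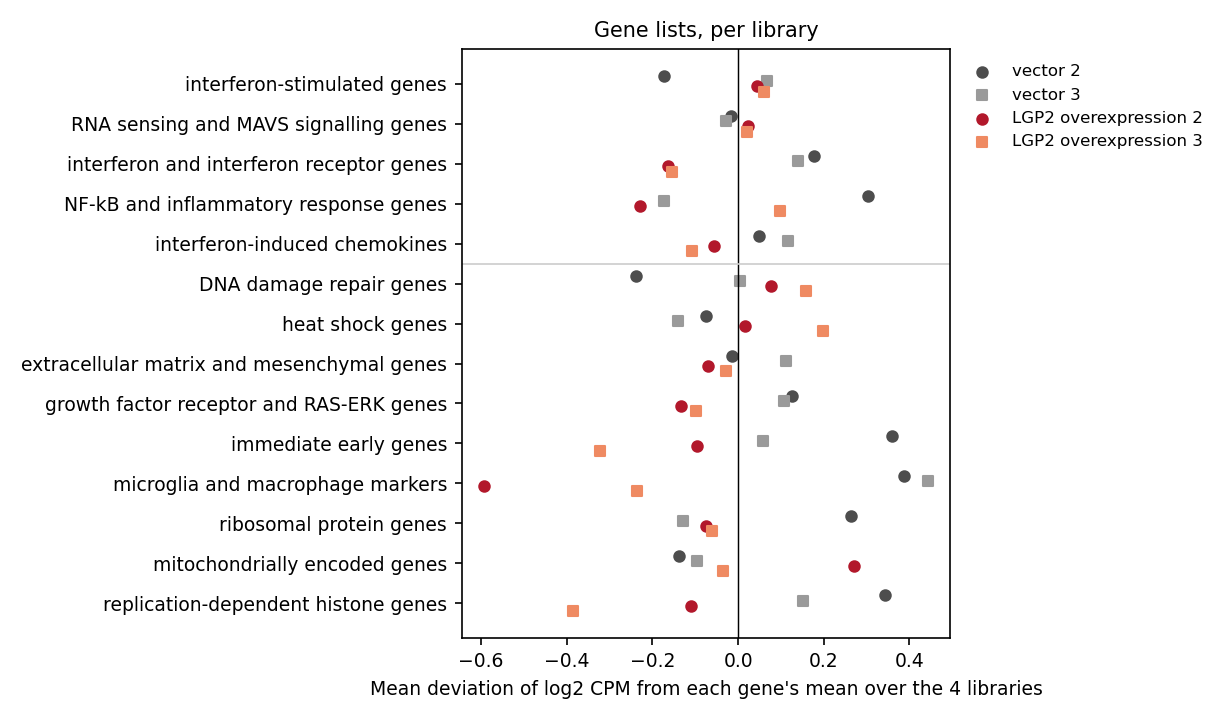
Mean deviation of log2 CPM from each gene's mean over the 4 libraries, for the 5 RNA sensing, interferon and inflammation lists (top) and the 9 lists that passed camera (below the line), with 1 point per library. For immediate early genes the vector libraries lay at 0.36 and 0.06 and the LGP2 overexpression libraries at -0.09 and -0.32, while for ribosomal protein genes the groups overlapped.

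Across the 36 lists, 3 passed as higher and 6 as lower with camera's preset correlation, 0 passed with an estimated correlation (smallest adjusted p = 0.735) and 0 passed with fry (smallest adjusted p = 0.356 for a common direction and 0.535 for change in either direction). The estimated correlation was below the preset for the matrix, RAS-ERK and microglia lists (-0.018, -0.029 and -0.036), and these lost their calls all the same. For the other lists that passed it ran from 0.10 to 0.95. The few residual degrees of freedom of that test can thus end a call without any correlation between genes, so its result decides neither way. The scores of the groups did not overlap for 20 of the 36 lists, where chance gives 33.3% for a single list and the lists, taken from the same 4 libraries, are not independent. Leaving out 1 library turned the sign of the median for 1 of the 9 lists that passed and for 18 of the 27 that did not, 16 of these without vector replicate 2. Among the 758 different genes on the lists, 0 passed over all genes tested by edgeR, 37 were higher and 28 lower at an unadjusted p under 0.05, 1 was called by DESeq2 (EGR1) and 0 by limma-voom. Members of 6 lists passed adjusted over the list alone. The median of all tested genes was -0.01.

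Proliferation, survival and metabolism lists did not pass, nor did the stress lists besides heat shock genes. The median log2 fold change was 0.02 for 35 S phase and DNA replication genes (adjusted p = 0.383), 0.04 for 35 G2 and M phase genes (0.233), -0.06 for 22 p53 target genes (0.292) and 0.02 for 29 apoptosis regulators and caspases (0.597). Without vector replicate 2 the S phase median was -0.0053 and the p53 median 0.0043, without LGP2 overexpression replicate 3 the S phase median was also -0.0053, and without vector replicate 3 they were 0.05 and -0.10. For 32 of the S phase genes and 32 of the G2 and M phase genes the 95% interval excluded a 2-fold change in either direction, and the proliferation antigen MKI67 was at 61.1 ± 19.1 CPM in vector and 62.8 ± 8.72 CPM with LGP2 (SD, n = 2 per group). Among these stress lists, the median was 0.07 for 19 endoplasmic reticulum stress genes (adjusted p = 0.124) and -0.09 for 22 integrated stress response genes (0.151). Among metabolic lists it was -0.06 for 32 hypoxia and glycolysis genes (0.233), 0.07 for 23 cholesterol synthesis genes (0.233), -0.08 for 30 nuclear oxidative phosphorylation genes (0.111) and -0.08 for 5 metallothionein genes (0.597). Without vector replicate 3 camera also called the G2 and M phase genes higher (adjusted p = 9.9e-05) and the integrated stress response, hypoxia and glycolysis, oxidative phosphorylation and metallothionein lists lower (adjusted p = 9.7e-05, 9.9e-05, 8.9e-05 and 0.0137). The hypoxia and glycolysis list was also called lower without LGP2 overexpression replicate 2 (adjusted p = 0.0400). Without vector replicate 2 these 5 directions turned and none passed, with medians of -0.07 for G2 and M phase, 0.0018 for integrated stress response, 0.10 for hypoxia and glycolysis, 0.02 for oxidative phosphorylation and 0.27 for metallothionein genes (adjusted p from 0.113 to 0.405). Directions also turned for G2 and M phase genes without LGP2 overexpression replicate 2 (median -0.03), for hypoxia and glycolysis and metallothionein genes without LGP2 overexpression replicate 3 (0.0077 and 0.06), and for the apoptosis list, by its test alone, without vector replicate 3 (adjusted p = 0.913).

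Adhesion, invasion and developmental signalling lists did not pass either. The 28 matrix protease and invasion genes had a median log2 fold change of -0.05 against a mean of 0.04, with a downward test direction (camera, adjusted p = 0.903), and the 26 integrins and adhesion receptors a median of -0.02 against a mean of 0.09, with an upward one (0.597). The 23 TGF-beta response genes had a median of 0.01 against a mean of -0.11 and a downward test direction (0.129), and the 24 YAP and TAZ target genes a median of -0.17 (0.111). CCN1, a matricellular protein on both of these lists, was at 1023 ± 655 CPM in vector and 303 ± 148 CPM with LGP2 (SD, n = 2 per group) and passed adjusted over the list alone in each (adjusted p = 0.0416 and 0.0434), but not over all genes tested (0.895). CCN1 was at a log2 fold change of -0.89 without vector replicate 2 and -2.30 without vector replicate 3. Without LGP2 overexpression replicate 2 it was at -2.37, and without LGP2 overexpression replicate 3 at -1.33. Both lists passed as lower without vector replicate 3 (adjusted p = 0.0123 and 3.9e-06) and among genes with at least 5 CPM in 2 libraries (0.00795 for each), while without vector replicate 2 the YAP and TAZ list turned upward (median 0.11, adjusted p = 0.974). The 24 Notch and Wnt target genes had a median of -0.01 against a mean of 0.01 and a downward test direction (adjusted p = 0.597). The test direction turned upward for the protease list without vector replicate 2 and without LGP2 overexpression replicate 3 (adjusted p = 0.631 and 0.876), and for the Notch and Wnt list without LGP2 overexpression replicate 3 (0.984).

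Markers of cell identity gave no call beyond the microglia list. Of 24 glioma stem cell genes 14 were analysed here, with a median of -0.06 against a mean of 0.11 and a downward test direction (camera, adjusted p = 0.597), which turned upward without vector replicate 2 (0.933) and without LGP2 overexpression replicate 2 (0.705). CD44, a hyaluronan receptor, was at 1925 ± 386 CPM in vector and 1705 ± 68.3 CPM with LGP2, and the aldehyde dehydrogenase ALDH1A3 at 832 ± 54.9 and 820 ± 106 CPM (SD, n = 2 per group). The median was -0.28 for 12 astrocyte markers (adjusted p = 0.233), 0.05 for 7 neuronal markers (0.597), 0.22 for 5 oligodendrocyte lineage markers (0.512) and 0.63 for 7 endothelial markers (0.484). Without LGP2 overexpression replicate 3 the neuronal median turned to -0.20, and without vector replicate 2 the astrocyte median was -0.10. Without LGP2 overexpression replicate 3 and without vector replicate 3 the oligodendrocyte median was 0.05 and 0.47 and the endothelial median 0.29 and 0.96, and the endothelial median was -0.28 over the members with at least 5 CPM in 2 libraries. The astrocyte filament gene GFAP was at 0.362 ± 0.0235 and 0.600 ± 0.132 CPM (SD, n = 2 per group). Of 17 markers of HEK293 cells, the line from which 293T derives, 8 were analysed here, with a median of -0.15 (adjusted p = 0.412) that turned to 0.04 without vector replicate 2 and 0.0038 without LGP2 overexpression replicate 2. EPCAM, an epithelial adhesion molecule, had 102 and 11 counts in vector and 2 and 0 with LGP2 and passed adjusted over that list alone (adjusted p = 0.0261), but not over all genes tested (0.937). CD44, ALDH1A3, GFAP, MKI67 and EPCAM were chosen after their values were seen, as was CCN1.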

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

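GC and length offsets and the exclusion of genes that share exons were chosen after seeing the data. DHX58 was called under all 13 alternatives, with log2 fold changes from 5.82 to 6.42 and adjusted p up to 0.0415. The count of higher genes, 3 in the fit reported, and of lower genes, 0, became 14 and 9 with DESeq2's Wald test, 4 and 2 with limma-voom, and 4 and 2 among genes with at least 5 CPM in 2 libraries. It was 1 and 0 with no filter and 1 and 0 without genes that share exons, where both other called genes were left out by construction. DESeq2 size factors, upper-quartile scaling, GC and length offsets, a log2 fold change of at least 1 and an adjusted p under 0.01 each left 3 and 0. Leaving out 1 library gave 1 to 291 higher and 1 to 141 lower genes, with the lone library of a group assumed to vary like those of the other group. Of the 9 lists that passed, 0 passed with an estimated correlation and 0 with fry, and leaving out 1 library gave 3 to 16 lists. Across all genes, samples of the same replicate number did not deviate together (correlation 0.03, with only 2 numbers). This does not exclude a shared day or batch that moved some genes. Scores of immediate early genes were higher in replicate 2 than in replicate 3 of both groups (0.36 and 0.06, -0.09 and -0.32). Those of mitochondrially encoded genes were so only with LGP2 (0.27 and -0.03, against -0.14 and -0.10 in vector). Adding a replicate block gave 5 higher and 3 lower genes, CCN1 among the lower (adjusted p = 0.00141), and 10 lists, 8 of them among the 9. The TGF-beta response and the YAP and TAZ lists were added (adjusted p = 0.0112 and 0.00869) and the microglia and macrophage markers were not called (0.0521). The filter of at least 5 CPM also called both added lists, and left the histone and microglia lists with too few genes to test. Over the alternatives, 48 named genes besides DHX58, 36 of them chosen after their values were seen for a small p in the direction of their list, kept direction and side of the threshold 576 times, kept direction and gained a call 14 times or lost one 4 times, and turned 15 times. For set tests these numbers were 375, 15, 39 and 28. Except where the construction is named, causes are not tested in this section, and tests of some of them are given under the other observations. Alternatives for normalized values, among them pseudocounts and quantile normalization, were not run because the values are counts.

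A turn means a change of direction, called or not. Of the 43 turns, 31 came from leaving out 1 library, 18 of them vector replicate 2, and 2 involved a call, for CXCL8 and the ribosomal protein genes without vector replicate 2. Without 1 library, log2 fold changes ran from -0.83 to 0.77 for CXCL8, -0.94 to 0.95 for TMEM119, -0.79 to 0.14 for EPHA2, -0.14 to 0.33 for MAVS, -0.083 to 0.28 for JAK1, -0.23 to 0.066 for SOD2, -0.14 to 0.11 for BST2, -0.11 to 0.25 for CXCL10, -0.51 to 0.033 for RPL37A and -0.44 to 0.028 for RPL11. Among lists that turned, adjusted p without 1 library ran from 1.1e-13 to 0.204 for ribosomal protein genes, 0.0263 to 0.839 for interferon-stimulated genes, 2.4e-06 to 0.999999 for NF-kB, 9.9e-05 to 0.999999 for G2 and M phase, 9.7e-05 to 0.532 for integrated stress response, 9.9e-05 to 0.787 for hypoxia and glycolysis, and 8.9e-05 to 0.569 for oxidative phosphorylation. It ran from 3.9e-06 to 0.974 for YAP and TAZ, 0.0137 to 0.824 for metallothionein, 0.516 to 0.913 for apoptosis, 0.523 to 0.956 for matrix protease, 0.260 to 0.984 for Notch and Wnt, and 0.287 to 0.933 for glioma stem cell genes. Lists that turned among genes with at least 5 CPM were those of interferon receptors (adjusted p = 0.743), integrins (0.898) and HEK293 markers (0.981). With GC and length offsets the antigen presentation (0.880), integrin (0.806), Notch and Wnt (0.908) and metallothionein (0.566) lists turned, as did BST2 (0.14) and CXCL10 (-0.067). The matrix protease list turned with fry (0.992) and without genes that share exons (0.857), and TMEM119 with limma-voom (0.0068).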

Other observations

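Among single genes outside the called ones, TXNIP, which encodes a thioredoxin-binding protein that restrains glucose uptake, was at 597 ± 100 CPM in vector and 336 ± 17.1 CPM with LGP2 (SD, n = 2 per group). PPARGC1A, which encodes a coactivator of mitochondrial genes, was at 1.79 ± 0.0223 and 5.49 ± 1.03 CPM, and CIP2A, an inhibitor of the phosphatase PP2A, at 19.9 ± 3.00 and 39.2 ± 6.26 CPM (SD, n = 2 per group). Their log2 fold changes were -0.83 (SE 0.17), 1.61 (SE 0.31) and 0.98 (SE 0.20). DESeq2 called all of them (adjusted p = 4.9e-04, 0.0205 and 0.00377) and edgeR none (0.713, 0.648 and 0.713). In the simulations, with 200 genes changed, DESeq2 made a median of 26 false calls, against 14 higher and 9 lower genes called here. Its calls may therefore include false ones. They share no exon with another gene in GENCODE 29, and they were chosen after their values were seen. IL6, an inflammatory cytokine, had 15739 counts in vector replicate 2 and 4213, 3431 and 5463 in vector replicate 3 and LGP2 overexpression replicates 2 and 3. BEST1 had 7105 counts in vector replicate 2 and 185, 105 and 140 in the others in the same order, and AC004922.1 had 3458, 8, 4 and 15.

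The tests of the partners of AC007192.1 and of the calls made by DESeq2 alone were chosen after the results were seen, and the GC and length offsets and the exclusion of shared exons were added after the data had been examined. For the histone list, the reading of the test without vector replicate 2 was made stricter afterwards, because leaving out another library also shrank the median and ended the call.

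Across genes, log2 fold changes fell with GC content (Spearman's rho -0.34) and rose with transcript length (0.18), and offsets brought these to -0.0016 and -0.02. The trend as the whole cause is argued against for 6 of the lists that passed, which passed again with offsets and kept most or all of their medians, at -0.41 for immediate early genes, 0.28 for mitochondrially encoded genes, -0.41 for histone genes, -0.16 for the RAS-ERK list, -0.15 for the matrix list and 0.26 for heat shock genes. The trend may account for the ribosomal protein genes, whose median went from -0.15 to -0.066 and whose call ended (adjusted p = 0.128). The trend stays open for DNA damage repair genes, at 0.12 against 0.17 with the call kept. LGP2 overexpression replicate 2 alone may account for the mitochondrial call, whose median went from 0.26 to 0.12 without it. That median stayed at 0.24 or beyond without any other library. For immediate early genes the median went from -0.42 to -0.22 without vector replicate 2, so that library may account for part of their fall. Neither list passed with an estimated correlation (camera, adjusted p = 0.735 for each). Without vector replicate 2 the immediate early and mitochondrially encoded genes still passed (camera, adjusted p = 4.0e-04 for each). That fit holds a single vector library, and the preset correlation of 0.01 was below the estimated 0.25 and 0.87. These p-values therefore cannot exclude vector replicate 2 alone as the source of either call. The mitochondrial median hardly changed without it (0.24 against 0.26), while the immediate early median kept its direction but shrank. Vector replicate 2 may account for the DNA damage repair call (camera, adjusted p without it 0.121). The same holds for the ribosomal call, whose median turned to 0.07 without vector replicate 2 (0.204) and stayed at -0.15 or beyond without any other library. For the histone genes vector replicate 2 cannot be told apart from LGP2 overexpression replicate 3, since the call ended without either (0.119 at a median of -0.28 and 0.0504 at -0.35). For every list a response to LGP2 and a difference in culture or handling between the groups stay open and untested.

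AL121594.1 and AC007192.1 rose by 56.4 and 43.6 CPM, and reads moved from genes that share their exons are a candidate explanation. For AC007192.1 the summed partners IFI30 and PIK3R2 had a log2 fold change of -0.47 (95% interval -0.80 to -0.15), which holds the fall of -0.60 that such a move predicts, while the whole locus stood at 0.08 (-0.25 to 0.41). For AL121594.1 the summed partners PRORP and PSMA6 had -0.32 (-0.71 to 0.07), an interval that holds both the predicted -0.18 and 0. Most of this sum is PSMA6 (414 CPM in vector, against 58.3 CPM for PRORP), so the sum can hardly show a move of this size. PRORP alone had -0.55 (-1.03 to -0.08) and PSMA6 alone -0.29 (-0.67 to 0.09). A move of reads therefore cannot be told apart from an added transcript there. A change of transcript structure in the overexpressing cells stays open for AL121594.1 and AC007192.1, as the counts hold no junctions.

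Reads split among genes that share exons may also add to the spread between libraries and to calls that rest on the tool. Of 20 genes called by DESeq2 and not by edgeR, 18 had a GENCODE match and 10 of these (55.6%) shared an exon, against 17.6% of 20274 other genes (odds ratio 5.84, two-sided Fisher's exact p = 3.2e-04). Genes are not independent replicates in that test. The coefficient of variation was 23.0% over 14565 tested genes with no shared exon and 34.0% over 2914 with one, a ratio of 0.676, which lay between the bounds set for and against the explanation. Among genes in the top 3 expression deciles it was 11.9% and 13.99%, and no biological explanation was tested.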
